A study of Mus musculus with 285 samples.

How the data were processed

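Skeletal muscle of 285 F2 mice was profiled on a 2-colour oligonucleotide array with 23560 probes. The mice came from intercrosses of F1 animals of the inbred strains C57BL/6J and C3H/HeJ, made in both directions. They ate chow with 4% fat until 8 weeks of age and then a Western diet with 42% fat and 0.15% cholesterol for 12 weeks, and were killed at 20 weeks after a fast of 12 hours. Per the labels, RNA of each mouse was labelled with Cy3 and compared with a common pool, labelled with Cy5, of equal portions of RNA from every sample. The labels name neither the muscle dissected nor the sex, genotype or cross direction of single mice. All 285 mice therefore formed 1 group and no groups were compared. The only order among them that was used is the mouse number, from 51 to 362. The order of deposit differs from it and was not studied.

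The deposited values were read as log10 ratios of mouse over pool, a unit the labels do not state. Array medians lay between -0.0222 and 0.0173, so the arrays had been centred or dye-normalised before deposit by steps the labels leave out. The values were bounded at exactly 2 and -2 on the deposited scale, which is 100-fold in log10, with 471 values at the upper and 178 at the lower bound. Because the pool is the mean of the mice, the mean linear ratio of a gene should lie near 1. It was 0.796 for the Y-linked gene Eif2s3y read as log10 of mouse over pool and 23.2 with the sign turned, and 0.942 against 3.43 for Kdm5d. For base 2 the Eif2s3y means were 0.751 and 1.92. The slope of each probe's mean on its variance was -0.311 ± 0.0577 (bootstrap SE, 200 resamples of the mice), which has the sign of mouse over pool. Some pairs of arrays correlated below -0.3, down to -0.744. The labels state the dyes but not the sign of the ratio. Mouse over pool was kept because the means of the Y-linked genes and the sign of the slope point to it. Negative correlations can arise under it, since single mice can lie on opposite sides of a pool of all mice. A noise-free ratio would give -0.347 in base 2, -0.5 in base e and -1.15 in base 10, so the slope alone does not settle the base. Folds and log2 values below hold for base 10. In base 2 every log2 value would shrink by the same factor, while correlations, clusters and tests would stay as they are.

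Probes with a value on at least 80% of the arrays were kept, 23510 in all, and 0.0972% of values were missing and set to the probe mean. Of the probes, 13653 carried 1 gene symbol, 48 carried several and 9859 carried none. Symbols were updated through the Entrez identifier for 12650 probes. Probes of one gene were averaged, giving 11622 named genes and 9890 unnamed probes, and values were converted to log2. Probe pairs of one gene correlated over mice with a median Pearson r of 0.235, and of 0.712 in the 1268 pairs with the largest SD, against -0.00238 for random pairs. The number of arrays limits the precision. The files hold no signal intensities or background, so signal over background is unknown.

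Before the data were examined, 32 gene lists, the tests and most alternatives were fixed. The lists covered slow and fast fibre genes, glycolysis, oxidative phosphorylation, fatty acid oxidation, lipogenesis, sterol synthesis, the FoxO and fasting response, both arms of the circadian clock, heat shock, immediate early genes, interferon response, MHC class II, ribosome, proteasome, proliferation and denervation. Cell type lists covered matrix, white and brown adipocytes, macrophages, lymphocytes, erythroid cells, endothelium, Schwann cells, satellite cells, smooth muscle, tendon, keratinocytes, hepatocytes and the sex chromosomes. Coherence of a list was the median pairwise Pearson r of its members over mice, set against 10000 random lists matched on SD decile, with a one-sided p and Benjamini-Hochberg adjustment over the 31 lists with at least 4 measured members. A list score was the mean z value of the members. For 16 pairs of scores, Pearson r and Spearman rho were tested with two-sided permutation tests of 100000 shuffles of the mice and adjusted over the 16 pairs, and r was computed again without the 2 mice farthest from the median of the first score. A score was taken to fall into separate clusters where a normal mixture with more than 1 component gained over 10 in BIC. The means had to lie over 3 SD apart, with at least 5% of mice in each component. The rule fixed beforehand for scores had no such minimum share. Without it, interferon, lipogenesis, brown adipocyte, proteasome, proliferation and hepatocyte scores would count too, with smaller components of 1.40 to 4.88% of mice. Their correlations are given over all mice of a pair and can rest in part on these few. For scores called with the minimum share, correlations between scores are given within clusters. Genes tracking a score were counted over all mice unless a cluster is named. The shuffles treat the mice as exchangeable, while many scores ran along the mouse number, so these p values are too small where both scores of a pair do.

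Each gene was regressed on 5 list scores, in SD units, with lmFit and eBayes of limma 3.58.1 under R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 and an absolute r of at least 0.3 were counted, and list members were left out of their own regression. With this many mice the minimum r decided the count. The fits treat mice as independent, so their SE and p are too small where gene and score both run along the mouse number. Gene order was taken from the GRCm38.p6 annotation, and pairs of genes up to 5 genes apart were compared with 1000 shuffled gene orders. Whole profiles of mice with consecutive numbers were compared with 100000 shuffles of the numbers. Separate clusters were also sought gene by gene. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

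Genes were named by a fixed rule. It took up to 4 members of each list by SD and up to 2 by correlation with the rest of the list, the 25 genes with the largest SD, and the 10 genes rising and the 10 falling most closely with each regressed score. It also took the 10 neighbouring pairs with the largest r whose symbols differ in their first 3 letters, the sex chromosome list, and the 10 genes with the widest separation of clusters. Other named genes are marked as chosen after their values were seen.

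On simulated data, lists given an r of 0.2 were called in 31 of 31 cases and lists given none in 0. In simulated regressions on the 5 scores over 11622 genes, 94 to 98% of genes with an absolute r of 0.3 passed the adjusted p and 42 to 64% also passed the minimum r, against 94 to 100% of genes with an r of 0.4. Between 4 and 18 of 11422 unchanged genes passed the adjusted p, and 0 passed both. Their noise was drawn independently for each mouse, without the drift along the mouse number seen in these data. False calls in the real arrays can therefore be more frequent. Clusters 4 SD apart were found in 100% of simulated genes. Their smaller cluster held more mice than the 5 to 10% found for most genes in separate clusters, a share that was not simulated.

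Alternatives fixed beforehand were arrays centred and scaled, probes with a value on every array, the probe with the largest SD per gene, mice without the 4 arrays titled as repeats, mice without the 12 arrays of outlying spread, the 143 lower-numbered and the 142 higher-numbered mice, removal of the first or the first 5 array-wide components, and other thresholds, windows and scores. Chosen after seeing the data were removal of a smooth trend along the mouse number (a cubic spline with 6 inner knots), the 209 mice outside numbers 51 to 90 and 271 to 310, the larger cluster of a score alone, other distances between mouse numbers, removal of the Y-linked genes, and neighbouring pairs without overlapping genes. No linkage analysis was made, since genotypes were not used here.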

Results

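The data were 285 arrays, each comparing skeletal muscle RNA of 1 F2 mouse with a pool of all mice. An F2 mouse carries a random mixture of the genomes of both grandparental strains, so the series measures how muscle gene expression varies among genetically mixed animals on one fatty diet. The SD of log2 values within an array had a median of 0.29 and ranged from 0.18 to 0.62 between arrays. Pairs of arrays correlated with a median r of 0.0751 over all probes, from -0.744 to 0.801, and 2.48% of pairs lay below -0.3.

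Among the 25 genes with the largest SD among mice were genes of the Y chromosome, of slow muscle fibres, of tendon and of fat, liver and blood cells. Whole groups did not vary that widely. The Y-linked translation factor gene Eif2s3y had the largest SD, 2.99 on the log2 scale over 285 mice, and the histone demethylase gene Kdm5d had an SD of 1.69, while the Y-linked Usp9y had an SD of 0.17, the slow fibre list member Myh6 of 0.12 and the tendon transcription factor gene Scx of 0.30, the last 2 chosen after their values were seen. Ucp1, the uncoupling protein of brown fat, had an SD of 2.01 and ranged from -3.11 to 6.16. Fabp1, the liver fatty acid binding protein, had an SD of 2.23, and the clotting genes Fgg and F2 had SDs of 1.81 and 1.30. Among muscle genes, the slow myosin heavy chain gene Myh7 had an SD of 1.74, the slow troponins Tnnt1 and Tnnc1 of 1.53 and 1.51, the slow myosin light chain Myl2 of 1.42, the stress-induced ankyrin repeat gene Ankrd1 of 1.49 and the myogenic factor gene Myod1 of 1.38. The tendon genes Kera and Chad had SDs of 1.56 and 1.33, and the B cell receptor gene Cd22 and the macrophage elastase gene Mmp12 of 1.40 and 1.41.

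Of the 25 genes with the largest SD, the remaining ones were Lhx1, Slc12a1, Gbp2b, Slc15a2, Ces1c, Pttg1, Sh2d4a, Itgad and Pold3, with SDs from 1.33 to 2.36. Lhx1, Slc12a1, Fabp1 and Pold3 reached the upper bound of the deposited values, 6.64 on the log2 scale, in at least 1 mouse. Lhx1, Slc12a1 and Pold3 reached the lower bound, -6.64, as well. The 95th percentile of Lhx1 lay at the upper bound, so its SD rests in part on bounded values. In all, 335 of 11622 named genes were at least 2-fold from the pool in at least 10% of the mice, and so were 191 unnamed probes. The median gene had an SD of 0.21, with 5th and 95th percentiles of 0.11 and 0.56. The named count was 6 with the values read in base 2 and 21 in base e.

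Genes of one function or cell type varied together in 26 of the 31 lists tested. Slow fibre genes had a median pairwise r of 0.492 over 12 members, against 0.0161 in random lists, and Tnnt1 correlated with the rest of its list at 0.952. Fast fibre genes, with 5 measured members, had a median r of 0.238, and the calcium store protein gene Casq1 ran against the others at -0.256. The 12 genes of oxidative phosphorylation reached 0.506, led by the cytochrome oxidase subunits Cox8b (0.847 with the rest) and Cox4i1 (0.835). Fatty acid oxidation reached 0.210, with Cpt2 and Hadhb at 0.714 and 0.679, and glycolysis 0.219, with Pkm at 0.793. Lipogenesis reached 0.155, where fatty acid synthase (Fasn) and stearoyl-CoA desaturase (Scd1) had SDs of 0.81 and 0.74.

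Stress and regulatory lists were coherent too, least firmly the Arntl arm of the clock. Immediate early genes, which respond within minutes to stimuli, had a median r of 0.369 and included Egr1 and Btg2 with SDs of 1.14 and 1.02. Heat shock genes had a median r of 0.266, with an SD of 1.04 for the chaperone gene Hspa1a. The interferon response had 0.299, led by Rtp4 at 0.891 with the rest, and the FoxO and fasting genes 0.166, led by the transcription factor gene Cebpd at 0.702. The clock lists had 0.117 for the Arntl arm and 0.102 for the opposite arm, where Per2 had an SD of 0.96. The Arntl arm lost its call in the lower-numbered (0.110, adjusted p = 0.0633) and the higher-numbered mice (0.0178, 0.271), outside numbers 51 to 90 and 271 to 310 (0.0750, 0.0923), with the first 5 array-wide components removed (0.0582, 0.116) and against random lists not matched on SD (adjusted p = 0.0920). Ribosomal protein genes had 0.379, proteasome genes 0.294 and proliferation genes 0.0952.

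Markers of cell types other than muscle fibres ranged from the most coherent list to weak ones. Tendon genes had the highest median r of all lists, 0.774 over 11 members, with the proteoglycan gene Fmod at 0.962 with the rest. The tendon score fell into clusters of 205 and 80 mice, so part of this r can lie between clusters. Its medians were highest in mouse numbers 271 to 290 (1.23) and 291 to 310 (1.08). Scores of keratinocyte (265 and 20 mice), immediate early (269 and 16) and heat shock genes (262 and 23) fell into clusters too. So did those of lymphocyte (270 and 15), MHC class II (270 and 15), white adipocyte (271 and 14) and slow fibre genes (58 and 227). Part of the r of each of these lists can lie between clusters as well. Matrix genes had 0.453, with Col6a3 at 0.850, macrophage genes 0.408, with the Fc receptor chain Fcer1g at 0.911, lymphocyte genes 0.418, with the B cell receptor chain Cd79b at 0.916, and MHC class II genes 0.483, with H2-Aa at 0.824. Smooth muscle had 0.228, hepatocyte genes 0.210, Schwann cell genes 0.207 with the myelin gene Mbp at an SD of 0.77, white adipocyte genes 0.183, keratinocyte genes 0.115 and endothelial genes 0.0677. Hepatocyte genes lost their call without the 12 arrays of outlying spread (0.0641, adjusted p = 0.277) and outside numbers 51 to 90 and 271 to 310 (0.142, 0.0722), white adipocyte genes in the lower-numbered mice (0.0580, 0.116), and keratinocyte genes in the higher-numbered mice (0.0405, 0.105) and with the probe of largest SD per gene (0.102, 0.0615). Permutation p for the 26 lists ranged from 0.0001, the smallest 10000 random lists can give, to 0.0269, and adjusted p from 0.000282 to 0.0321.

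Not past the threshold were sterol synthesis (median r 0.0307, adjusted p = 0.0728), erythroid genes (0.0954, 0.0728), denervation genes (0.0259, 0.177), brown adipocyte genes (0.0644, 0.222) and satellite cell genes (0.00944, 0.427). Each of these lists gained a call in some settings. Erythroid genes did with arrays scaled (0.127, 0.0334), in the lower (0.162, 0.0244) and higher numbers (0.116, 0.0172), outside numbers 51 to 90 and 271 to 310 (0.138, 0.0387), with the trend removed (0.119, 0.0134), against unmatched random lists (0.0473) and given 1 (0.270, 0.000141) or 5 components (0.269, 0.000135). Sterol synthesis did with arrays scaled (0.0349, 0.0480), without outlying arrays (0.0467, 0.0286), in the higher numbers (0.0434, 0.0239), with the trend removed (0.0346, 0.0413) and given 1 (0.0546, 0.00941) or 5 components (0.0572, 0.00609). In the higher numbers and given 1 or 5 components, denervation genes (0.0621, 0.0404 and 0.0301) and brown adipocyte genes (0.131, 0.0782 and 0.224) passed, and satellite cell genes did given 5 (0.0699, 0.00973). Single members of these lists still moved together, such as the beta globins Hbb-b1 and Hbb-b2 at 0.823 and 0.819 with the rest, and Cidea at 0.730 with the rest of the brown adipocyte genes. The sex chromosome list had 3 measured members and was not tested. Genes are not independent replicates, so the p describes these arrays.

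**Figure D1:**
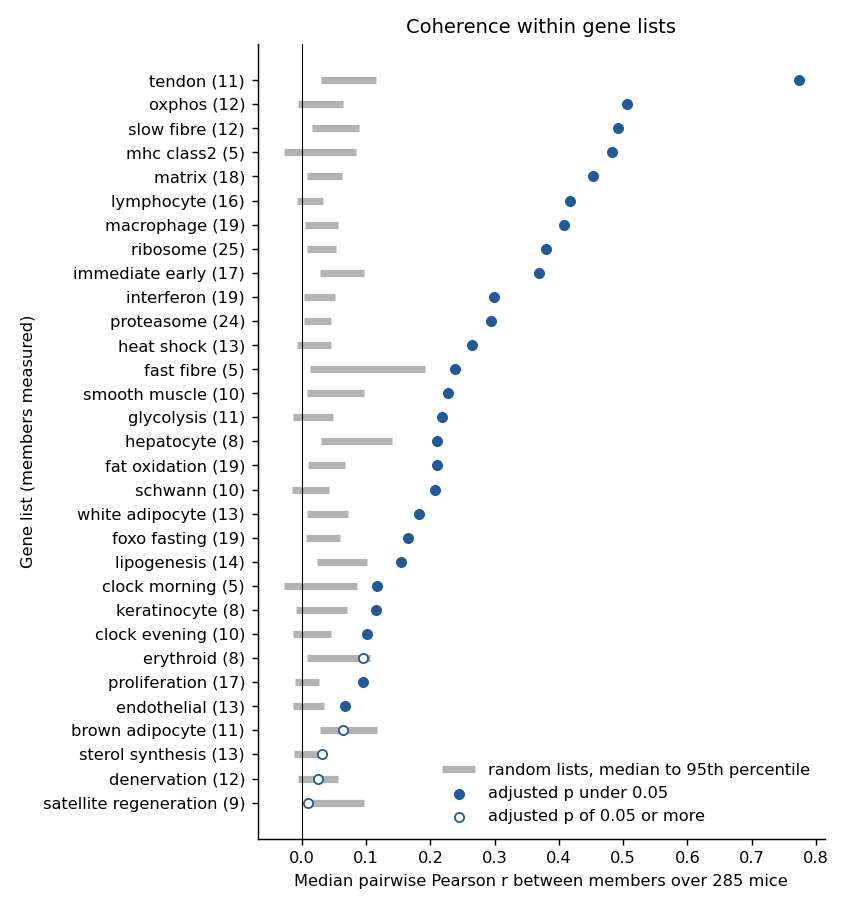
Median pairwise Pearson r of the members of each of 31 gene lists over 285 mice, with the number of measured members in brackets. Grey bars run from the median to the 95th percentile of random lists matched on SD, filled points are lists past an adjusted p of 0.05, and tendon lies highest at 0.774.

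Slow fibre genes separated the mice into a lower cluster of 58 and a higher one of 227. Low values lay in runs of the mouse numbers. The median of Myh7 was -5.13 in numbers 51 to 70, -3.19 in 71 to 90, -3.09 in 271 to 290 and -3.21 in 291 to 310, against -0.44 to 0.29 in every other run of 20 numbers. In the same runs the position genes Pitx1 and Irx5 had medians from -0.64 to -0.50 and from -1.98 to -1.58, against -0.35 to 0.34 and -0.03 to 0.51 elsewhere. The homeobox gene En1 had medians from 0.96 to 1.46 in these runs, but was also high in 311 to 330 (0.90) and 331 to 350 (0.64), so it did not mark the same runs as Myh7 and Irx5. Single mice overlapped: Myh7 was -0.06 in mouse 287 inside the runs and -3.43 in mouse 219 outside. Pitx1 was 0.16 in mouse 87 inside. These runs, their width and these 4 genes were chosen after the values were seen.

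**Figure D2:**
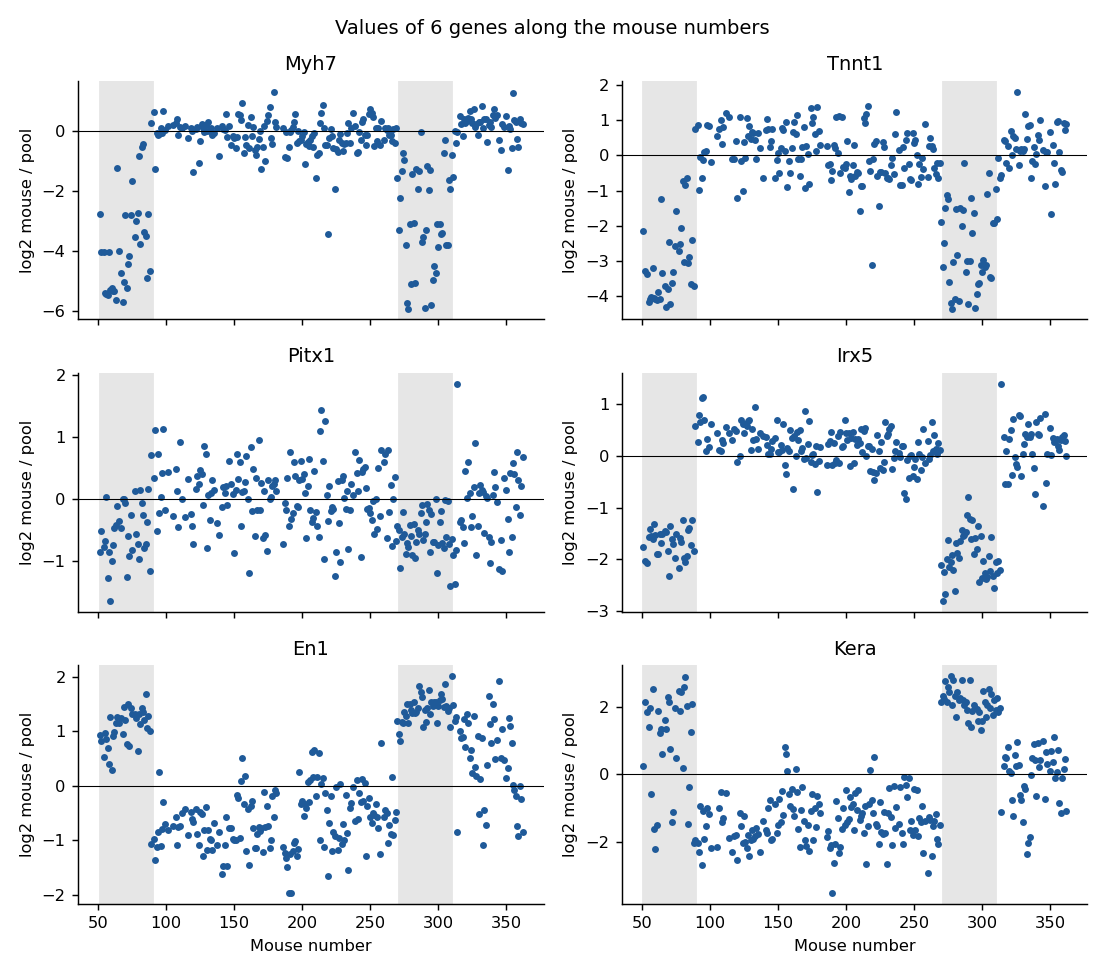
Log2 ratio of mouse over pool for 6 genes in each of 285 mice, 1 point per mouse, along the mouse number, with numbers 51 to 90 and 271 to 310 shaded. Myh7, Tnnt1, Pitx1 and Irx5 have low medians and En1 high ones in the shaded runs, while single mice overlap. The genes shown were chosen after their values were seen.

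Along the slow fibre score, 275 genes rose and 349 fell. The LIM domain genes Fhl1 and Fhl2, which encode partners of the sarcomere, rose by 0.45 ± 0.02 and 0.51 ± 0.02 log2 per SD of the score (SE, 285 mice), and Pdlim1 and Ablim1, which bind actin, by 0.44 ± 0.02 and 0.29 ± 0.02. Ldhb, the heart-type lactate dehydrogenase subunit, rose by 0.37 ± 0.02, with an r of 0.569 within the larger cluster and 0.589 within the smaller. Spred2, Cyp2c29, Ces5a, Pla2g12a and Ift81 rose as well. Among falling genes were the secreted Wnt regulator gene Dkk3, with a coefficient of -0.72 ± 0.04, the T-box gene Tbx1 with -0.62 ± 0.04, the sodium-calcium exchanger gene Slc8a1 with -0.33 ± 0.02, the tendon gene Kera with -0.88 ± 0.08, and Twist1, Tiam1, Penk, Lefty1, Hoxc6 and En1. Adjusted p by limma lay between 1.49e-62 and 6.36e-23 for these 20 genes.

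Of the fixed lists, 9 of 11 tendon and 8 of 19 macrophage genes fell with the slow fibre score over all 285 mice. These counts pool both clusters. The 5 fast fibre genes had a median r of -0.0232 with the score. Adjusted over the list alone, the counts were also 9 and 8. Within the larger cluster of 227 mice 115 genes rose and 103 fell. There 149 of the 624 genes passed again in the same direction and 22 had the opposite sign. In the 209 mice outside the runs 165 rose and 218 fell. Of the 624 genes, 146 passed again there in the same direction and 83 had the opposite sign. The limits of the runs are rough: mice 270, 311, 312 and 313 outside them had Irx5 values of -2.11, -2.26, -2.03 and -2.20, and mouse 89 inside had 0.58. With a smooth trend along the numbers removed, 189 rose and 173 fell. Without that removal, Kera and En1 had r values of 0.155 and 0.153 within the smaller cluster, against -0.265 and -0.252 within the larger. For the named rising genes r within the smaller cluster ran from 0.0516 for Cyp2c29 to 0.686 for Fhl1. Among the named falling genes, Tiam1 had -0.515 there, Tbx1 -0.0999 and Hoxc6 -0.0565.

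Slow and fast fibre scores were unrelated within the larger cluster, with r = 0.0280 and rho = 0.00916 over 227 mice (permutation p = 0.677 and 0.891, adjusted p = 0.677 and 0.891), and r was 0.0453 without the 2 extreme mice. In the smaller cluster of 58 mice r was 0.0345 (permutation p = 0.8). Slow fibre and oxidative phosphorylation scores rose together in the larger cluster, with r = 0.183 and rho = 0.201 (permutation p = 0.00533 and 0.00237, adjusted p = 0.00775 and 0.00345) and r = 0.189 without the 2 mice. The smaller cluster gave r = 0.0585 (permutation p = 0.663), and the relation lost its call in the 142 higher-numbered mice (r = 0.0534), outside the runs (0.0978), with arrays scaled (0.0904), with the trend removed (0.102), given 1 (0.10) or 5 components (0.127) and with first components as scores (0.104). Slow fibre and Schwann cell scores gave r = -0.109 and rho = -0.132 over 227 mice (permutation p = 0.1 and 0.0472, adjusted p = 0.134 and 0.0630), r = -0.124 without the 2 mice, and r = 0.276 in the 58 mice (permutation p = 0.0358, adjusted p = 0.0835).

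Most matrix and tendon genes rose with the macrophage score. Along the macrophage score 897 genes rose and 145 fell. The myeloid genes Igsf6, Clec4a1, Clec10a and Dok2 rose by 0.28 ± 0.01, 0.25 ± 0.01, 0.47 ± 0.02 and 0.26 ± 0.01 log2 per SD, the nucleotide receptor gene P2ry6 by 0.38 ± 0.02, the folate receptor gene Folr2 by 0.43 ± 0.02, the leukocyte tetraspanin gene Cd53 by 0.63 ± 0.03, and Ptpro, Ccl9 and Lrrc33 by 0.43 ± 0.02, 0.32 ± 0.01 and 0.28 ± 0.01. Falling genes had smaller coefficients, from -0.18 ± 0.02 for the water channel gene Aqp4 to -0.04 ± 0.01 for Il17f, with Hoxa5, Smyd2, Myh14, Dhx34, Hdhd5, Map3k15, Rab3ip and Eif2b1 between. Adjusted p by limma ranged from 1.41e-90 to 7.08e-11 for these 20 genes.

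Rising lists were matrix with 15 of 18 members, tendon with 9 of 11, interferon with 9 of 19, proliferation with 7 of 17, lymphocyte with 6 of 16 and MHC class II with 3 of 5, and 6 of 12 slow fibre genes fell. Adjusted over the list alone, these counts were 15, 9, 9, 7, 6, 3 and 6. The score correlated with that of matrix at r = 0.617 and rho = 0.596 over 285 mice, and at 0.608 without the 2 extreme mice. It correlated with MHC class II at r = 0.576 and rho = 0.589 in the larger cluster of 270 mice (0.565 without 2), where the 15 others gave r = 0.366 (permutation p = 0.18). Interferon and macrophage scores correlated at r = 0.398 and rho = 0.398 (0.397 without 2), and matrix and endothelial scores at r = 0.401 and rho = 0.387 (0.405 without 2). Each permutation p was 1e-05, the smallest that 100000 shuffles can give, with adjusted p of 1.60e-05 for r and 1.78e-05 for rho. Of the 1042 genes counted, 903 were counted again in the 143 lower-numbered and 939 in the 142 higher-numbered mice, but with the first 5 array-wide components removed only 436 were and 115 had the opposite sign, while the falling count was 349 and 508 there and 94 with arrays scaled.

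The white adipocyte score had a smaller cluster of 14 mice with high values, and over all mice 647 genes rose and 467 fell along it. Lgals12, a galectin of fat cells, rose by 0.52 ± 0.02 log2 per SD, the amine oxidase gene Aoc3 by 0.54 ± 0.02, the phosphatase gene Acp5 by 0.57 ± 0.02, the lipid antigen presenter gene Cd1d1 by 0.65 ± 0.03 and the FGF21 co-receptor gene Klb by 0.46 ± 0.02, with r of 0.732 for Lgals12 and 0.608 for Klb within the larger cluster. Gnai1, Tmem45b, Smoc1, Ywhab and Hacd2 rose by 0.41 ± 0.02, 0.56 ± 0.02, 0.32 ± 0.01, 0.23 ± 0.01 and 0.42 ± 0.02. Falling genes were Wrap73, TTC19, Twf2, Ptges3l, Card19, Rangrf, Faf1, Mrpl16, Snupn and ZSWIM7, with coefficients from -0.13 to -0.06. Adjusted p by limma for the 20 genes ranged from 3.24e-67 to 1.96e-15.

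Along this score over all 285 mice, 9 of 14 lipogenesis, 6 of 10 Schwann cell and 5 of 11 brown adipocyte genes rose. So did 6 of 16 lymphocyte and 3 of 5 MHC class II genes. Falling were 3 of 12 oxidative phosphorylation and 3 of 13 heat shock genes. The counts adjusted over the list alone were the same. Within the larger cluster of 271 mice the score correlated with lipogenesis at r = 0.453 and rho = 0.469 (0.444 without 2 mice) and with brown adipocyte genes at r = 0.312 and rho = 0.264 (0.294 without 2), each with a permutation p of 1e-05 and adjusted p of 1.60e-05 for r, and adjusted p of 1.78e-05 and 3.20e-05 for rho. In the 14 mice r was 0.631 (permutation p = 0.0154, adjusted p = 0.0538) and 0.791 (permutation p = 0.00074, adjusted p = 0.00518). White adipocyte and macrophage scores gave r = 0.0876 and rho = 0.0768 over 271 mice (permutation p = 0.148 and 0.205, adjusted p = 0.169 and 0.234; r = 0.0682 without 2) and r = 0.307 in the 14 (permutation p = 0.287). Call and sign of that pair depended on the setting, with r = 0.170 with arrays scaled (adjusted p = 0.00701), 0.182 outside numbers 51 to 90 and 271 to 310 (0.0162), 0.133 with the trend removed (0.0414), 0.201 with first components as scores (0.00104) and -0.316 given 5 components (2.29e-05). The larger cluster alone gave 245 rising and 163 falling genes, the lower-numbered mice 253 and 221 and the higher-numbered mice 1065 and 1248. Of the 1114 genes, 382 were counted again in the larger cluster, 306 in the lower numbers (20 had the opposite sign), 1081 in the higher numbers and 231 given 5 components (192 had the opposite sign).

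Along the FoxO and fasting score 1018 genes rose and 788 fell. The amino acid transporter gene Slc7a8 rose by 0.58 ± 0.03 log2 per SD, the kinase genes Sik1 and Map3k6 by 0.66 ± 0.04 and 0.51 ± 0.03, the elongation factor gene Ell2 by 0.45 ± 0.03, and Tcp11, Anxa13, Tango2, Apbb3, Anapc16 and 6430548M08Rik by 0.17 ± 0.01, 0.34 ± 0.02, 0.23 ± 0.01, 0.37 ± 0.02, 0.19 ± 0.01 and 0.48 ± 0.03. Cpeb4, a regulator of translation, fell with a coefficient of -0.30 ± 0.03, and the small heat shock protein gene Hspb3 with -0.20 ± 0.01, as did INTS2, Zbtb5, Dact2, Zfp3, Psme2b, Aktip, Zcchc17 and Antkmt with coefficients from -0.18 to -0.10. Adjusted p by limma for these 20 genes lay between 5.95e-67 and 6.69e-25.

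Of the fixed lists, 7 of 17 immediate early genes rose and 1 fell with this score, 6 of 19 fatty acid oxidation genes rose and 9 of 25 ribosomal protein genes fell, and adjusted over the list alone the counts were 7, 6 and 9. The score correlated with that of fatty acid oxidation at r = 0.286 and rho = 0.315 over 285 mice (permutation p = 1e-05 for both, adjusted p = 1.60e-05 and 1.78e-05), and at 0.326 without the 2 extreme mice. It rose along the mouse number, with r = 0.509 and rho = 0.493 (permutation p = 1e-05, adjusted p = 1.92e-05 over 23 lists) and r = 0.50 without 2 mice. With a smooth trend along the numbers removed, 306 genes rose and 99 fell, and 328 of the 1806 genes were counted again. With the first 5 array-wide components removed, 367 were and 414 had the opposite sign. The correlation with fatty acid oxidation was no longer past the threshold with the trend removed (r = 0.106, adjusted p = 0.101). It also lost its call in the 142 higher-numbered mice (r = 0.105, adjusted p = 0.312) and outside numbers 51 to 90 and 271 to 310.

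The scores of both arms of the circadian clock ran against each other. They correlated at r = -0.254 and rho = -0.263 over 285 mice (permutation p = 1e-05 for both, adjusted p = 1.60e-05 and 1.78e-05), and at -0.237 without the 2 extreme mice. Along the score of the arm that holds Per2 and Dbp, 276 genes rose and 324 fell. These 2 members had r of 0.514 and 0.534 with the rest of their list, but Hlf and Nr1d1 had 0.0218 and -0.0121. Arntl, the activator of the clock, fell with a coefficient of -0.30 ± 0.02 log2 per SD (r = -0.609), the only one of the 5 measured genes of its arm to pass, and the median r of these 5 genes with the score was -0.0879. The sterol carrier gene Stard3 rose by 0.16 ± 0.01 (r = 0.661), the nuclear receptor corepressor gene Nrip1 by 0.26 ± 0.03 and the drug exporter gene Abcc1 by 0.15 ± 0.02, with Slc45a4, Aff1, Foxo6, Syne1, Smim41, Itgb5 and Ing2 between 0.07 and 0.16. Ormdl2, a regulator of sphingolipid synthesis, and the chaperone gene Hsp90b1 fell with coefficients of -0.13 ± 0.01 each, as did Gmcl1, Miga2, Olfm1, Metrnl, TRMT5, Timm8a1 and Cfap20, from -0.21 to -0.11. Adjusted p by limma for these 20 genes lay between 3.27e-33 and 3.41e-14.

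Of the fixed lists, 4 of 11 glycolysis genes rose with this clock score and 5 of 17 proliferation and 4 of 19 macrophage genes fell, with the same counts adjusted over the list alone. The score was not related to that of the FoxO and fasting genes over all mice (r = 0.0954, rho = 0.0682, permutation p = 0.109 and 0.253, adjusted p = 0.134 and 0.270, r = 0.0928 without 2 mice). That relation took either sign with the setting, -0.198 with a trend along the numbers removed (adjusted p = 0.00115) and 0.346 with the first component of each list as its score (adjusted p = 1.60e-05). The lower-numbered mice gave 640 rising and 748 falling genes, and the rising count was 478 with arrays scaled. Of the 600 genes, 520 were counted again in the lower numbers and 326 in the higher numbers (4 had the opposite sign). With the trend removed 361 were, and given 5 components 263 were (5 had the opposite sign).

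**Figure D3:**
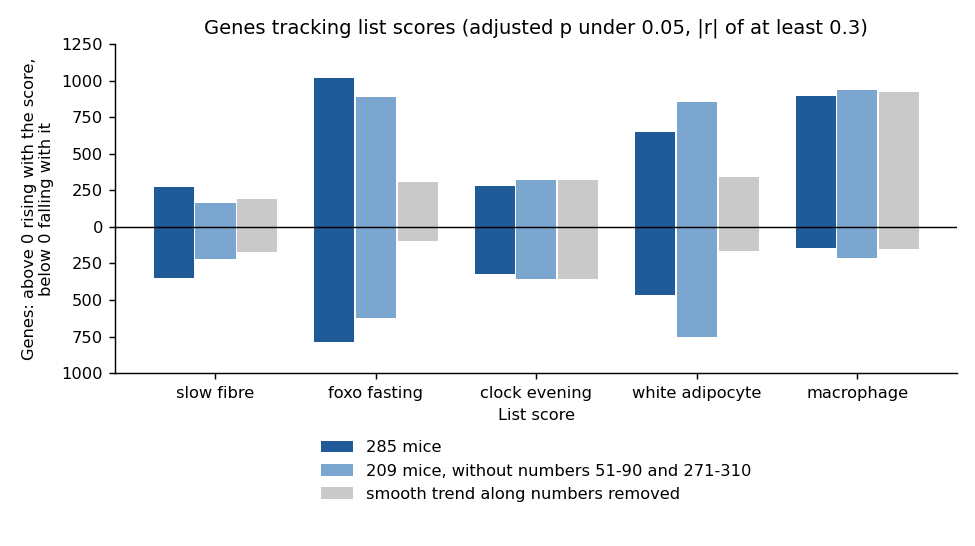
Number of genes rising (above 0) and falling (below 0) with each of 5 list scores at an adjusted p under 0.05 and an absolute r of at least 0.3, in 285 mice, in the 209 mice outside numbers 51 to 90 and 271 to 310, and with a smooth trend along the mouse number removed. The FoxO and fasting score has 1018 and 788 genes in 285 mice, and 306 and 99 with the trend removed.

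Oxidative phosphorylation and fatty acid oxidation scores correlated at r = 0.425 and rho = 0.438 over 285 mice (permutation p = 1e-05 for both, adjusted p = 1.60e-05 and 1.78e-05; r = 0.411 without 2 mice), with r = 0.399 in the lower-numbered and 0.668 in the higher-numbered mice. Ribosome and oxidative phosphorylation scores correlated at r = 0.623 and rho = 0.551 (the same p; r = 0.605 without 2 mice), at 0.764 and 0.219 in the lower and higher numbers, and at -0.0155 (adjusted p = 0.794) given the first array-wide component, which held 15.4% of the variance. Fast fibre and glycolysis scores gave r = 0.0554 and rho = 0.0876 (permutation p = 0.353 and 0.141, adjusted p = 0.376 and 0.173; r = 0.0734 without 2 mice), and the sign turned with the probe of largest SD per gene (r = -0.189, adjusted p = 0.00199).

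**Figure D4:**
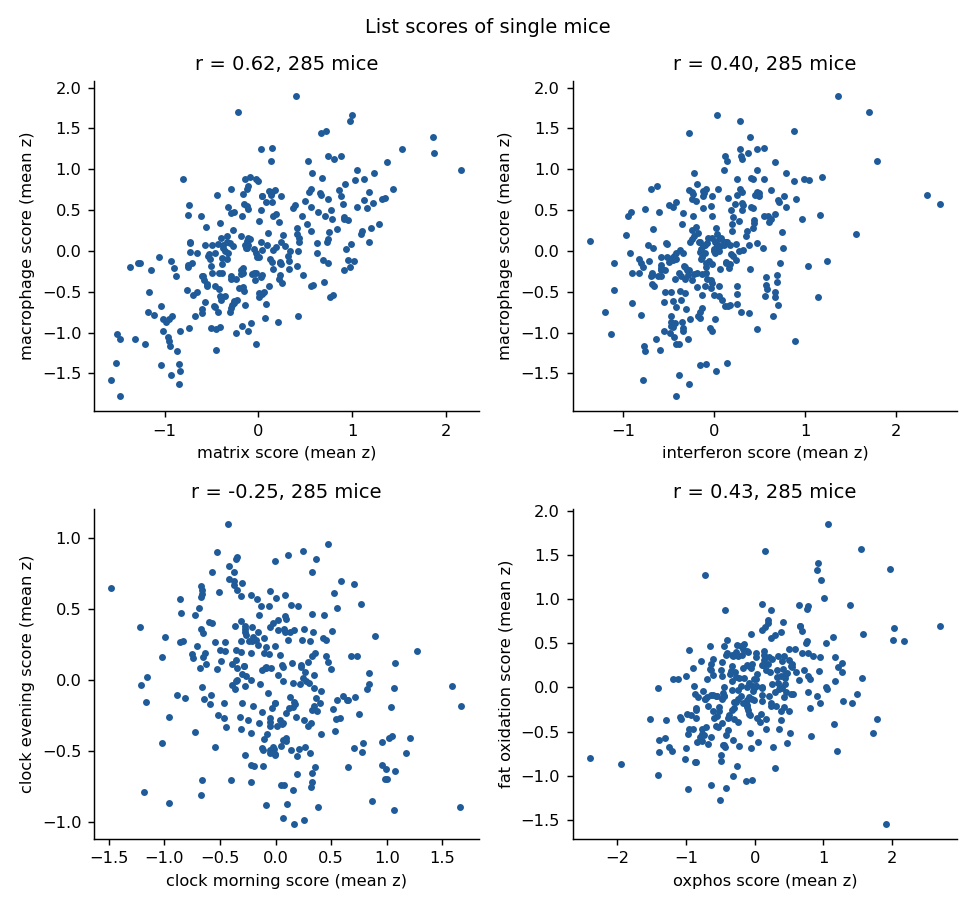
List scores of single mice, each the mean z value of the members, for 4 pairs of lists with 285 points each. Matrix and macrophage scores (r = 0.617), interferon and macrophage scores (0.398) and oxidative phosphorylation and fatty acid oxidation scores (0.425) rise together, and the 2 clock scores run against each other (-0.254).

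Genes lying near each other on a chromosome are inherited together in an F2 cross. Genotypes were not used, so whether this inheritance accounts for the correlation of neighbouring genes was not tested. Among pairs up to 5 genes apart whose symbols differ in their first 3 letters, the Y-linked Kdm5d and Eif2s3y had the largest r (0.964). Next came Ssty1 and Gm20747, also Y-linked (0.940), and the liver plasma protein genes Ahsg and Hrg on chromosome 16 (0.940). Chd2 and Akap13 on chromosome 7 (0.919) and the slow fibre genes Myl2 and Atp2a2 on chromosome 5 (0.910) followed. Cxcr5 and Cd3g on chromosome 9 (0.908) and Il2rb and Rac2 on chromosome 15 (0.891) are leukocyte genes. Phf1 and Bak1 on chromosome 17 (0.908), Syt13 and Hsd17b12 on chromosome 2 (0.902) and Zkscan8 and H4c11 on chromosome 13 (0.889) completed the 10. Over 53765 pairs up to 5 genes apart among 10817 genes, the mean r was 0.0282, against a mean of 0.00354 and a highest value of 0.00690 in shuffled gene orders. An absolute r of at least 0.3 was reached by 20.9% of pairs, against 18.6% and at most 19.2% when shuffled (permutation p = 0.000999 for both, the smallest that 1000 shuffles can give). The mean r fell from 0.0453 in adjacent genes to 0.00413 at 101 to 200 genes apart, and was 0.00318 between chromosomes. Without pairs sharing the first 3 letters of their symbols it was 0.0232.

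**Figure D5:**
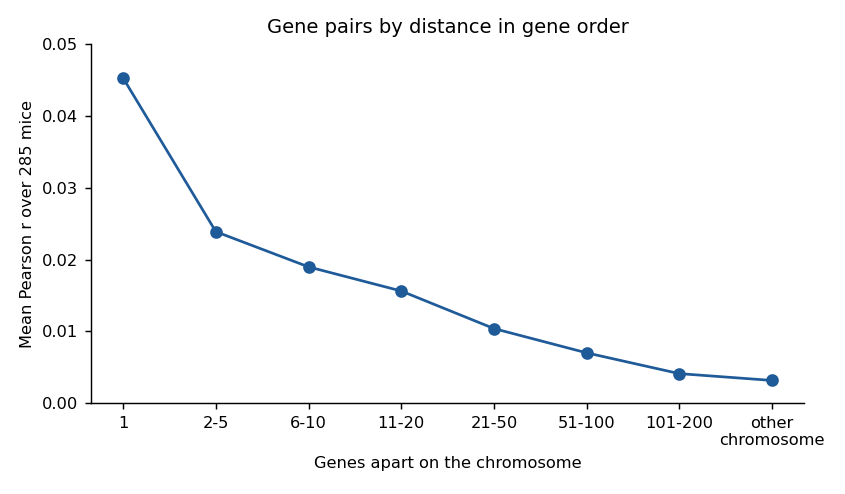
Mean Pearson r over 285 mice of gene pairs on one chromosome, by the number of genes apart, with pairs on other chromosomes at the right. The mean falls from 0.0453 for adjacent genes to 0.00318 for pairs on other chromosomes.

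Mice with consecutive numbers had alike profiles. The mean r of their whole profiles was 0.273 over 262 pairs, against at most 0.0466 in 100000 shuffles of the numbers (one-sided permutation p = 1e-05, the smallest they can give). Numbers 2 to 5 apart gave a mean r of 0.194 and numbers over 150 apart -0.0932. The mean r of consecutive numbers was 0.0831 with a smooth trend along the numbers removed (permutation p = 1e-05). Of 23 list scores without separate clusters, 17 ran along the mouse number by rho at an adjusted p under 0.05. Besides the FoxO and fasting score, rho was 0.463 for Schwann cell genes and 0.405 for lipogenesis, and -0.478 for proteasome, -0.457 for ribosome, -0.443 for erythroid and -0.422 for oxidative phosphorylation genes, with r of 0.443, 0.366, -0.396, -0.431, -0.420 and -0.403 and of 0.434, 0.360, -0.386, -0.420, -0.416 and -0.395 without 2 mice (permutation p = 1e-05 and adjusted p = 1.77e-05 for each rho).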

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

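Removal of a smooth trend along the mouse number, mice outside numbers 51 to 90 and 271 to 310, the larger cluster of a score alone, distances of 6 to 10, 11 to 50 and over 150 between mouse numbers, removal of the Y-linked genes and neighbouring pairs without overlapping genes were chosen after seeing the data. Of 439 values under alternatives, 342 kept their direction and call or stayed within 1.5 times the count. The cause of a change was not tested, and the lower and higher numbers differ in more than the number of mice. Neighbouring genes kept their call in every alternative run, with a mean r from 0.0196 to 0.0453, and so did consecutive mouse numbers, from 0.0831 to 0.280. Signal over background is unknown, so its effect was not studied.

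The slope of mean on variance was -0.541 in the most variable probes and -0.252 without sex chromosome genes. Genes 2-fold from the pool numbered 6 in base 2, 21 in base e, 91 at 25% of mice and 1832 at 1.5-fold. Profiles of numbers over 150 apart had a mean r of -0.0932, below the shuffled mean of -0.00281. The one-sided test asks only for higher values (permutation p = 1), so it does not judge this lower value. Coherence turned sign for 2 lists that had no call: denervation in the lower numbers (-0.00749), and satellite cells there (-0.0223) and without outlying arrays (-0.00547).

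Correlations of scores changed as follows. With arrays scaled, slow fibre with oxidative phosphorylation was 0.0904 and lost its call, and clock with FoxO (0.137) and white adipocyte with macrophage (0.170) gained one. In the higher numbers, slow with fast fibre was -0.0917, slow fibre with oxidative phosphorylation 0.0534, FoxO with fatty acid oxidation 0.105 and clock with FoxO -0.0136. Outside the runs, slow fibre with oxidative phosphorylation was 0.0978, FoxO with fatty acid oxidation 0.145 and white adipocyte with macrophage 0.182. With the trend removed, these were 0.102, 0.106 and 0.133, clock with FoxO was -0.198 and slow fibre with Schwann cells 0.0813. Given the first array-wide component, slow with fast fibre was -0.0433, slow fibre with oxidative phosphorylation 0.10 and ribosome with oxidative phosphorylation -0.0155. Given 5 components, these first 2 were -0.0579 and 0.127, fast fibre with glycolysis 0.197, clock with FoxO -0.0974, white adipocyte with macrophage -0.316 and slow fibre with Schwann cells 0.0156. With first components as scores, slow fibre with oxidative phosphorylation was 0.104, fast fibre with glycolysis -0.289, clock with FoxO 0.346 and white adipocyte with macrophage 0.201. The probe of largest SD gave -0.189 for fast fibre with glycolysis.

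Counts of genes along scores, rising then falling, moved by over 1.5 times as follows. At an absolute r of 0.5 they were 51 and 23 for slow fibre, 155 and 44 for FoxO, 5 and 10 for clock, 135 and 6 for white adipocyte and 266 and 0 for macrophage. That 0 is from limma with the r minimum, and 2803 genes fell at no minimum. With no minimum they were 1345 and 1676, 2771 and 3160, 1949 and 1707, 2048 and 3007, and 1783 and 2803. Given 5 components, slow fibre had 496 rising, FoxO 517 and 322, white adipocyte 294 and 220 and macrophage 545 and 267. Given 1 component, 460 fell for FoxO and 420 for macrophage. The lower numbers gave 555 and 733 for slow fibre, 640 and 748 for clock, 253 and 221 for white adipocyte and 349 falling for macrophage. The higher numbers gave 536 and 280 for FoxO, 418 rising for clock, 1065 and 1248 for white adipocyte and 508 falling for macrophage. With arrays scaled, 478 rose for clock, 266 fell for white adipocyte and 94 for macrophage. In the larger cluster, slow fibre had 115 and 103 and white adipocyte 245 and 163. Outside the runs, slow fibre had 165 and 218, and 752 fell for white adipocyte. With the trend removed, 173 fell for slow fibre, FoxO had 306 and 99 and white adipocyte 343 and 164.

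Genes in separate clusters numbered 175 with means over 4 SD apart, 142 with at least 10% of mice in each, 517 with arrays scaled and 186 given 5 components. Of the genes named along scores, 1303 of 1340 values under alternatives kept their call, 37 lost it and 0 turned sign. The smaller cluster of a score was not among these alternatives. Within that of the slow fibre score Kera and En1 had the opposite sign (r = 0.155 and 0.153). Of all genes counted, given 5 components, 414 of 1806 had the opposite sign for FoxO, 192 of 1114 for white adipocyte and 115 of 1042 for macrophage, and in the lower numbers 113 of 1806 for FoxO. List coherence kept its side in 338 of 372, gained a call in 21 and lost it in 10. The SD of named genes stayed within its bootstrap error in 913 of 1317 values.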

Other observations

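The tests of macrophage clusters, of scaling, distance and trend for consecutive mouse numbers, and of fast fibre genes were chosen only after the result was seen, as were the runs of mouse numbers, the further pairs of scores and the scores along the number.

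Of the 10 genes with the widest separation of clusters, the macrophage scavenger receptor gene Marco had a higher component with 6.67% of mice, 4.26 log2 units above the lower one. The lymphocyte genes Ptprcap, Ccr6, Cd79b, Cxcr5, Txk, Itgal, Pou2af1 and Il2rb had higher components with 6.32 to 7.02% of mice, and the skin gene Lor had one with 5.40%. In all, 805 of 11622 genes fell into separate clusters. Simulated normal data gave 0, and simulated data of a t distribution with 4 degrees of freedom gave 65. Both simulations were symmetric, so they cannot tell clusters from a one-sided tail of few mice. Of the 783 genes called with 2 components, 651 had a smaller component with 5 to 10% of mice, and 40 to 50% was reached by 14. By list, 9 of 16 lymphocyte genes, 8 of 12 slow fibre genes, 5 of 11 tendon genes, 5 of 17 immediate early genes and 2 of 3 sex chromosome genes fell into clusters, but only 1 of 19 macrophage genes did. With arrays scaled, 517 genes did, of which 323 were among the 805. Given 5 components, 186 did, of which 90 were among the 805.

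Among 239 further pairs of 23 list scores, 114 passed an adjusted p of 0.05, 56 of them positive and 58 negative. Since many scores ran along the mouse number, the pairs were tested again with a smooth trend along it removed: 109 passed, 84 of the 114 did so in the same direction and 4 had the opposite sign. Smooth muscle and endothelial scores correlated at r = 0.733 and rho = 0.717 over 285 mice (0.714 without the 2 extreme mice; 0.780 in the lower and 0.582 in the higher numbers). Smooth muscle and proteasome scores gave r = -0.547 and rho = -0.522 (-0.504 without 2; -0.730 and -0.171), macrophage and proliferation scores r = 0.473 and rho = 0.427 (0.444; 0.544 and 0.428), and clock and glycolysis scores r = 0.437 and rho = 0.415 (0.426; 0.506 and 0.353). Each permutation p was 1e-05, the smallest possible, with adjusted p of 4.78e-05 for r and 4.35e-05 for rho. With the trend removed r was 0.714, -0.468, 0.501 and 0.395 (rho 0.714, -0.459, 0.459 and 0.386; permutation p = 1e-05, adjusted p = 5.69e-05 for r and 6.83e-05 for rho). These 4 pairs were chosen after their values were seen.

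The lymphocyte score fell into clusters of 270 and 15 mice, and its median was 1.16 in mouse numbers 331 to 350, against -0.45 to 0.09 in the other runs of 20 numbers, in a run that also had the highest white adipocyte (0.488) and lowest oxidative phosphorylation median (-0.915). The macrophage score had no separate clusters (BIC gain -11.2), but it varied widely in all mice and 6 of 16 lymphocyte genes rose with it, so inflamed muscle with more macrophages stays open. With arrays centred and scaled the BIC gain of the lymphocyte score was 252, so their spread does not account for the clusters. A hypothesis is that some samples held lymphoid tissue: of 11 genes of lymph node stroma and sinuses, 4 fell into separate clusters (Madcam1, Cxcl13, Bst1 and Tnfsf11), against a median of 1 and a 95th percentile of 2 in random lists (p = 0.0077), though Ccl21a, Ccl19, Il7, Pdpn, Lyve1, Prox1 and Siglec1 did not. That count leaves open whether the same mice were high. As lymphocytes can express Tnfsf11 and Bst1 too, it cannot tell lymphoid tissue from lymphocytes within muscle. These 11 genes were not a list fixed before the data were examined. They can vary together more than genes drawn at random, so the p from random lists can be too small. Neither sex nor any other biological explanation from the design was tested for these clusters.

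The slow fibre score fell into clusters of 58 and 227 mice. Less muscle and more tendon in some samples would lower fast fibre genes too, but the 5 measured ones had a median r of -0.0232 with the score. With a smooth trend along the mouse number removed, the BIC gain went from 78.8 to -7.24 and the separation of the means from 3.82 to 2.01 SD, but such a trend takes up runs of 40 numbers whatever their cause and tells no causes apart. A hypothesis is that another muscle, or another part of one, may have been taken in these runs: of 57 genes of body and limb position, 12 tracked the score (Hoxa5, Hoxa11, Hoxc8, Hoxd4, Hoxd9, Hoxd10, Tbx15, Pitx1, Meis2, Emx2, Irx5 and Pax3), against a median of 3 and a 95th percentile of 7 in random lists (p = 0.0006). These 57 genes were not a list fixed before the data were examined. Position genes can track the score in blocks, as Hoxd4, Hoxd9 and Hoxd10 did (r = 0.556, 0.577 and 0.479). Genes drawn at random do so less, so the p from random lists can be too small. Sex and cross direction were not tested for this split and stay open.

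Profiles of consecutive mouse numbers were alike, with a mean r of 0.273. Scaling the arrays left 0.264, and regressing out Eif2s3y and Kdm5d left 0.223, which argues against array spread, and against the part of sex-dependent expression that follows these genes in a straight line, as the whole cause. Littermates or cage mates alone would leave little at numbers 11 to 50 apart, where the mean r was 0.0796 with a highest shuffled value of 0.00668. A slow drift alone would leave little with the smooth trend removed, where it was 0.0831 with a highest shuffled value of 0.0421. Litter, cage, sex, tissue dissection and hybridisation day may each add a part, and the labels give none of them.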
